A study of Homo sapiens with 30 samples.

How the data were processed

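The series holds 30 samples per the labels. Of these, 18 are first-stage libraries that compared 8 antibodies with 1 library each, and they are not analysed here. The 12 second-stage libraries are 3 control inputs, 3 control immunoprecipitations (IPs), 3 PCIF1 KO inputs and 3 PCIF1 KO IPs from MEL624 cells, the IPs all made with antibody 4. Per the labels' protocols, each preparation started from about 20 000 000 cells and 200 ug of total RNA, 5' end fragments were kept by an exonuclease that spares capped RNA, and libraries were made with a directional kit. Per the series' design text, second-stage libraries were planned at 35 M reads (inputs) and 18 M reads (IPs) on average.

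The deposited table holds log2 CPM (library-scaled read counts on a log2 scale) for the region of the transcription start of 16009 genes, with 1 column per library. Per the submitters' processing notes, HISAT2 2.0.4, SAMtools 1.7, deepTools 3.0.2, featureCounts, R 3.3.3 and edgeR 3.12.1 were used with build hg38, with no role or order stated. The window around each start, the annotation, the strand setting of the counting and any filter on genes are not given in the sources used here. The values themselves show that a small count, scaled to library size, was added before the logarithm. With an added count of 0.25, 100% of the values came out as whole reads within 0.01, and these reads give the depth of each library. Column sums lie near but not at the total that plain CPM would give, so that library sizes were scaled by some factor before deposit. A log2 difference on this scale understates the change of genes with few reads. Reads without molecular identifiers are not independent molecules.

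The table's columns carry the numbers 1 to 3, while the labels name replicates by letter, and nothing ties the numbers to the letters. Columns were therefore assigned to groups only, and the column number serves only as a name. Where the fixed rule for named genes pairs IP and input by letter, the column number was used in its place. For the comparison by first base, each IP was set against the mean of its genotype's 3 inputs.

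Gene names, classes, coordinates and starts come from GENCODE 44 on hg38. Of 16009 genes, 15903 matched by identifier and 14485 have a name. The 5' end of 3322 genes lies inside another gene on the same strand or within 200 bases of its start, and such reads are uncertain. Since strand handling in the counting is unknown, reads of antisense partners are uncertain as well.

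The groups, tests, gene lists, rule for named genes and most other settings were fixed before the data were examined. Genes were to be kept at a log2 value of at least 0 in at least 3 of 12 libraries, and all 16009 pass. In R 4.3.3, limma 3.58.1 fitted 4 group means over the 12 libraries with a mean-variance trend and no replicate block. From this fit came 5 contrasts, namely control IP minus control input, KO IP minus KO input, the difference of these (the interaction, called PCIF1-dependent enrichment), KO input minus control input, and KO IP minus control IP. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Reads were also simulated over 16009 genes from the control input profile, with the same spread for all genes. Known changes were planted only in better-covered genes, so that the shares do not hold for genes with few reads. The test recovered 62%, 93% and 100% of changes of 1.5-, 2- and 4-fold in control enrichment, and 42%, 71% and 98% in PCIF1-dependent enrichment. It called 2, 0, 2, 0 and 18 unchanged genes in the 5 contrasts, in the order above.

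Gene lists were tested with camera (limma) at a preset correlation of 0.01, with adjusted p over the lists of a contrast. Of 23 lists, 19 had at least 5 measured members. They are cytosolic ribosomal proteins, other 5' TOP mRNAs, mitochondrially encoded mRNAs, mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation, proteasome, spliceosome, adenosine methylation writers, erasers and readers, cap synthesis, binding and removal, melanocyte lineage, dedifferentiated melanoma, interferon-stimulated genes, p53 targets, integrated stress response, proliferation, cholesterol synthesis, glycolysis, replication-dependent histones, and HeLa and HEK293 lineage markers. Keratinocyte, fibroblast, leukocyte and endothelial markers had fewer. Members were counted at the adjusted p over all genes and at one adjusted over the list alone.

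Named genes followed a rule. PCIF1 came first, then the 10 largest differences each way in control enrichment, PCIF1-dependent enrichment and input change, and the 5 largest each way in KO enrichment. These were taken among genes with a name, an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the compared libraries. Up to 4 members of each list with the smallest adjusted p could be named too. Chromosome blocks and genes at their ends were chosen after their values were seen.

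The first base was read from the reference at the 5' end of the gene record. The mean enrichment of A-start genes minus that of other genes was compared per IP library by an exact two-sided permutation test, and calls were compared by Fisher's exact test. For the input change of PCIF1-dependent genes, groups with no input change were simulated 50 times, because the same inputs enter both contrasts. Blocks are runs of neighbouring protein-coding genes with a mean log2 CPM of at least 3 whose running median input change over 15 genes is at least 0.4 in size, set against 200 shuffled gene orders.

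The other settings chosen at that time were a stricter filter (log2 CPM of at least 3), a pseudocount of 1, centring on the median or on ribosomal protein mRNAs, quantile normalization, limma without trend or robust, a fit of the compared groups only, each library left out in turn, a minimum log2 difference of 1, an estimated correlation or fry for the lists, other definitions of the first base, and other definitions of the PCIF1-dependent class. Added after seeing the data were limma voom on the recovered reads, thinning to 1753164 reads per library, protein-coding genes only, a correction for GC content of the first 100 bases (15321 genes), replicate blocks by column number, RNA classes as lists, the canonical transcript start, genes outside the blocks, and a PCIF1-dependent class from 1 column number.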

Results

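MEL624 is a human melanoma cell line. Its 5' end fragments were profiled in control cells, which were wild-type cells given a random guide RNA, and in cells with a knockout (KO) of PCIF1, the enzyme that methylates the first transcribed adenosine next to the mRNA cap (m6Am). In this assay, m6Am-Exo-Seq, an exonuclease removes uncapped RNA fragments and an anti-m6A antibody, which also binds m6Am, pulls down methylated 5' ends from what is left. The 12 libraries used here form 4 groups of 3, namely control input, KO input, control immunoprecipitation (IP) and KO IP. The series' design text calls the 3 per group biological replicates, and does not say whether the KO replicates came from different clones. The limma p-values measure the spread between these samples. If the KO replicates share a clone, these p-values do not cover differences between clones, and KO and clone cannot be told apart. The term PCIF1-dependent names the contrast below and not a cause. The table listed 16009 genes.

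The reads behind the listed genes differed between groups. Control inputs held 3620471 reads on average (3232562 to 4094070) and KO inputs 3243409 (2836120 to 3544669). Control IPs held 4283508 reads on average (4035815 to 4625190) and KO IPs 2032714 (1753164 to 2177874), so that the KO IP libraries were the shallowest. Mitochondrial genes took 1.12% ± 0.133 of the reads in control inputs, 0.727% ± 0.112 in KO inputs, 0.946% ± 0.152 in control IPs and 1.95% ± 0.359 in KO IPs (SD, n = 3 each). Small nucleolar RNAs (snoRNAs) took 4.55% ± 0.353, 4.32% ± 0.171, 1.60% ± 0.0919 and 4.71% ± 0.158 in the same order. No pair of libraries within a group differed by less than the sampling noise. Enrichment below is the log2 difference IP minus input, given with the standard error (SE) of the fit and with p-values of the limma test adjusted over all genes.

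The targeted gene was read first, in every library. PCIF1 (ENSG00000100982, chromosome 20, 45934683 to 45948023 in hg38) gave 57.9, 52.5 and 49.4 CPM (the back-transformed log2 value) in the control inputs and 70.4, 78.0 and 77.1 CPM in the KO inputs. It gave 30.1, 23.7 and 26.0 CPM in the control IPs and 35.4, 41.0 and 28.7 CPM in the KO IPs. Its 5' end fragments were thus higher in KO inputs than in control inputs, by 0.50 ± 0.14 on the log2 scale (adjusted p = 0.0229). Fragments at the transcript start can lie outside the edited part of the gene, so that these values check nothing about the labels. PCIF1 itself was depleted by the antibody in control cells (-1.01, or 0.15 when libraries are centred on ribosomal protein mRNAs) and in KO cells (-1.11), and the difference of 0.11 ± 0.20 did not pass (adjusted p = 0.718).

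The first comparison asked which 5' ends the antibody enriched over input in control cells. HNRNPM, a pre-mRNA binding protein of the spliceosome, rose from 194 ± 20.1 CPM in the inputs to 1944 ± 59.8 CPM in the IPs (SD, n = 3), a log2 enrichment of 3.33 ± 0.09 (adjusted p = 4.43e-15). The peptidyl-prolyl isomerase gene PIN4 (3.09), the cytidine deaminase gene APOBEC3C (3.08) and the adaptor complex gene AP4S1 (2.93) were also among the 10 largest. CHMP1B (2.88), EPB41L2 (2.87), the isoprenoid synthesis gene FDPS (2.87), the activin subunit gene INHBA (2.87) the 3' end processing gene PCF11 (2.85) and PLEKHA4, which rose from 12.7 ± 1.99 to 101 ± 8.58 CPM, completed them. At the other end stood the ribosomal 5S pseudogene RNA5SP202 (-4.69), ZDHHC12 (-4.17), the ribosomal protein gene RPL12 (-4.03), the snoRNA SNORA73A (-3.88), the cytochrome oxidase assembly gene COX18 (-3.81) and RPL4 (-3.68). RPL12 went from 2229 ± 209 CPM in the inputs to 137 ± 16.5 CPM in the IPs. TMEM256-PLSCR3 (-4.08) and TMEM256 (-4.06) share a start and their reads cannot be told apart. The microRNA genes MIR4758 (-3.79) and MIR6873 (-3.70) and SNORA73A overlap the starts of LAMA5, WDR46 and RCC1 or SNHG3, so that their reads are uncertain too.

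Of 16009 genes, 8944 differed between control IP and control input, 4429 higher and 4515 lower in the IP. The libraries of both kinds did not overlap for 10643 genes (66.5%), where chance gives 10%. Centring every library on the ribosomal protein mRNAs, of which 64 of 79 start with C, moved the median of all genes to 1.14 and gave 10034 higher and 970 lower. Directions are therefore relative to the deposited scaling.

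Many ribosomal protein mRNAs were depleted in control cells. Of 79 measured, 57 were lower and 5 higher in the IP, with 58 lower and 6 higher adjusted over the list alone, and the median was -1.14 (0.02 when centred on these same mRNAs). Their set test gave adjusted p = 3.24e-15 (camera, preset correlation), and adjusted p = 0.212 with an estimated correlation. RPLP0 (-3.25 ± 0.10) and RPL27A (-3.08 ± 0.09) were examples. The other mRNAs with a 5' terminal oligopyrimidine (TOP) start had 15 lower and 0 higher of 20, the same adjusted over the list alone, with a median of -1.05 that turned to 0.11 under that centring. Their adjusted p was 2.67e-06 with the preset value, and adjusted p = 0.212 with an estimated correlation. GAS5, a snoRNA host gene (-2.87 ± 0.10), and the elongation factor gene EEF1A1 (-2.03 ± 0.13) were among them. Spliceosome genes went the other way, with 24 higher and 9 lower of 42 (24 and 10 adjusted over the list alone) and adjusted p = 0.00492, or adjusted p = 0.349 with an estimated correlation. SNRPD2 (1.69 ± 0.11) and SNRPG (1.60 ± 0.11), which encode Sm core proteins, rose, and the splicing factor gene SF3B2 fell (-1.97 ± 0.12).

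The same comparison within KO cells gives the enrichment in the absence of the cap methyltransferase. The executioner caspase gene CASP6 was enriched by 4.56 ± 0.34 (adjusted p = 7.98e-10), the non-coding RNA ZMPSTE24-DT by 4.17 ± 0.12 and the mitochondrial gene MT-ND2 by 3.92 ± 0.23, against 2.75, 2.49 and 1.68 in control cells. PLEKHA4 (3.84 ± 0.20) and the 7SK-binding protein gene LARP7 (3.83 ± 0.16) followed. HNRNPM kept a log2 enrichment of 3.29 in KO cells. COX18 (-3.98 ± 0.33), the ion channel gene TMEM38B (-3.95 ± 0.30), the lysosomal fucosidase gene FUCA1 (-3.53 ± 0.28), RNA5SP202 (-3.52 ± 0.27) and the coenzyme Q synthesis gene COQ9 (-3.50 ± 0.28) were the most depleted. All of these had few reads in the KO IPs, such as 4, 8 and 3 for FUCA1. Across all genes, 9512 differed, 4546 higher and 4966 lower in the KO IP. Centring on ribosomal protein mRNAs gave 7240 higher and 2415 lower, with a median of 0.53. Groups did not overlap for 9817 genes (61.3%), against 10% by chance.

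All 13 mitochondrially encoded mRNAs were higher in the KO IP than in its input (13 also adjusted over the list alone), with a median of 1.54, against 6 of 13 and a median of 0.09 in control cells. MT-ATP8 (3.26 ± 0.22) and MT-ND3 (2.16 ± 0.16) were examples, and many of their starts overlap a neighbouring mitochondrial gene. The set test gave adjusted p = 1.01e-06, and adjusted p = 0.856 with an estimated correlation. Of 79 ribosomal protein mRNAs, 48 were lower and 15 higher (48 and 16 adjusted over the list alone), with a median of -0.57 that becomes 0.03 when centred on them. The adjusted p was 0.000236, and adjusted p = 0.856 with an estimated correlation. Mitochondrial ribosomal protein mRNAs, which come from nuclear genes, had 43 lower and 13 higher of 75 (44 and 15 adjusted over the list alone), with adjusted p = 0.00202 and adjusted p = 0.856 with an estimated correlation. MRPS16 (-2.31 ± 0.10) and MRPL34 (-2.30 ± 0.10) were examples.

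Enrichment in control and KO cells went together across genes, with Pearson r 0.661 and Spearman rho 0.670 over 16009 genes, which are not independent replicates. These comparisons share no library. Both called 3036 genes higher, where 1258 would be shared by independent lists, and both called 3054 genes lower. A further 247 genes were higher in control and lower in KO cells, and 210 the reverse.

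The main question of the design is which 5' ends were less enriched in the KO. The difference of enrichment, control minus KO, was tested as an interaction. In what follows, more enriched in a genotype also covers less depleted there. RSRP1 had the largest difference, 2.91 ± 0.31 (adjusted p = 1.38e-06), with 25.3 ± 2.57 CPM in control IPs and 5.08 ± 0.951 CPM in KO IPs (SD, n = 3). ATP5F1B, the beta subunit of the mitochondrial ATP synthase, was the most abundant of the 10 largest. It gave 1439 ± 33.0 CPM in control IPs and 325 ± 27.3 CPM in KO IPs, while its inputs held 1710 ± 16.98 and 1729 ± 162 CPM, a difference of 2.16 ± 0.13 (adjusted p = 8.91e-09). TMEM14B (2.84 ± 0.28), the activin-binding follistatin-like gene FSTL3 (2.42 ± 0.58), the nucleic acid demethylase gene ALKBH1 (2.19 ± 0.31) and TOR1B (2.17 ± 0.32) were also less enriched in the KO. So were STK11IP (2.15 ± 0.37), the copper chaperone gene CCS (2.10 ± 0.40), the acyl-CoA thioesterase gene ACOT2 (2.10 ± 0.36) and TMEM184B (2.07 ± 0.25). Apart from ATP5F1B (602, 716 and 580 reads in the KO IPs), these genes had few reads there, such as 2, 6 and 12 for FSTL3 and 9, 8 and 4 for ACOT2. Their rank is therefore uncertain. In ATP5F1B, TMEM14B, FSTL3 and TOR1B the control IPs already lay below input. All 10 are protein-coding, and 9 of the 10 have an A as the first base of their canonical transcript, a definition chosen after the data were seen (46.1% of all protein-coding genes), and 6 by the gene record, as fixed before.

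**Figure D1:**
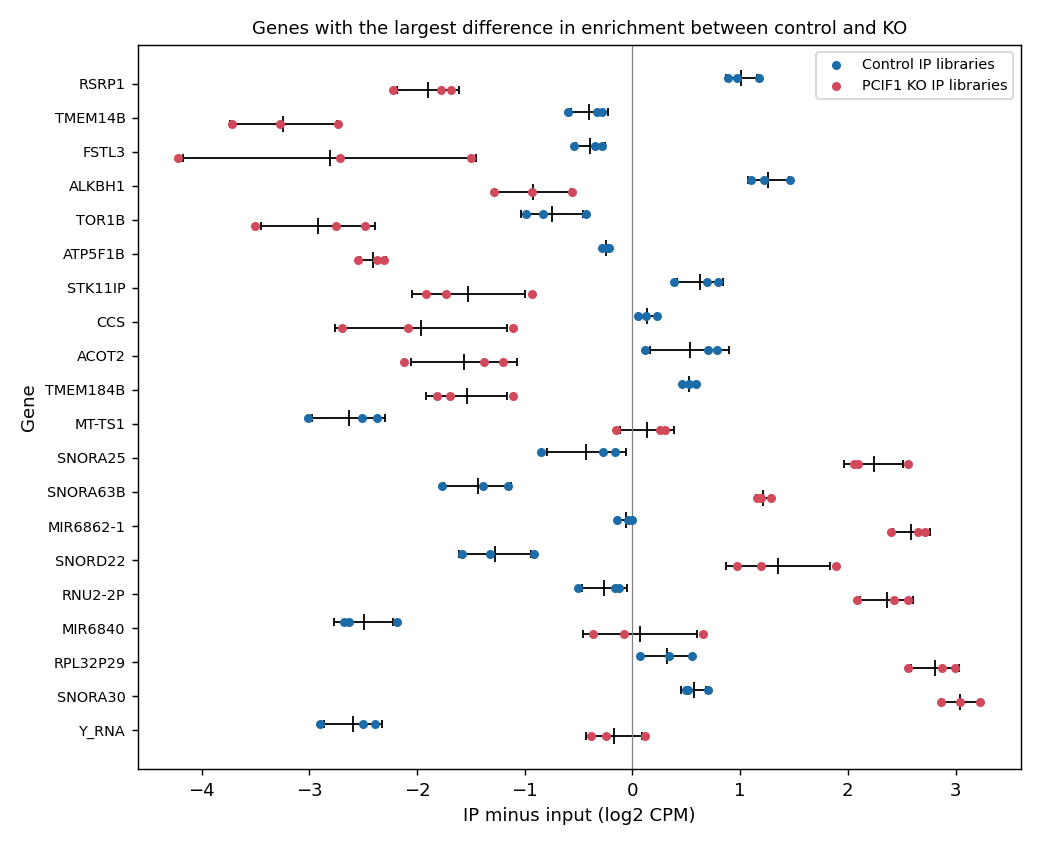
Log2 enrichment (IP minus input) of the 10 genes with the largest PCIF1-dependent difference in each direction, with each point 1 IP library against the mean of its genotype's 3 inputs, and black bars the mean and SD of 3 libraries. For ATP5F1B the control points lie above the KO points by 2.16 on average.

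The genes with the largest difference in the other direction, more enriched in KO than in control cells, were short non-coding RNAs. They were the mitochondrial serine tRNA MT-TS1 (-2.77 ± 0.28), the snoRNAs SNORA25 (-2.67 ± 0.35), SNORA63B (-2.65 ± 0.27), SNORD22 (-2.63 ± 0.33) and SNORA30 (-2.48 ± 0.26), the microRNA genes MIR6862-1 (-2.65 ± 0.33) and MIR6840 (-2.57 ± 0.43), and the U2 small nuclear RNA RNU2-2P (-2.62 ± 0.21). A Y RNA (-2.43 ± 0.36) and the pseudogene RPL32P29 (-2.49 ± 0.34) completed them. In 9 of these 10 the start lies in or near another gene on the same strand, so that their reads are uncertain, and by each of these definitions 3 start with A. Tested as a class after the data were seen, 132 of 211 snoRNAs were more enriched in KO cells and 0 in control cells, with a median of -1.60 (camera adjusted p = 1.82e-36, a call that holds with an estimated correlation).

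The interaction called 4605 of 16009 genes, 2522 more enriched in control and 2083 more enriched in KO cells. Of the 2522, 1226 were called enriched over input in control cells. The 3 control and 3 KO values did not overlap for 7165 genes (44.8%), against 10% by chance. Centring on ribosomal protein mRNAs moved the median difference of all genes to 0.61 and gave 5958 and 797.

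Several gene groups stood apart in this difference. Ribosomal protein mRNAs had 40 members more enriched in KO and 4 more enriched in control cells of 79 (44 and 5 adjusted over the list alone), with a median of -0.54, which becomes 0.02 when centred on them. RPS27A (-1.77 ± 0.13) and RPL5 (-1.71 ± 0.13) were examples, and the adjusted p was 5.49e-12, or adjusted p = 0.337 with an estimated correlation. Against input, the median of ribosomal protein mRNAs was -1.14 in control and -0.57 in KO cells, so that they were less depleted in the KO. The other TOP mRNAs had 11 of 20 more enriched in KO and 0 in control cells (12 and 0 adjusted over the list alone), GAS5 (-1.84 ± 0.14) and the nucleophosmin gene NPM1 (-1.22 ± 0.13) among them. Their adjusted p was 1.65e-07, or adjusted p = 0.174 with an estimated correlation. All 13 mitochondrially encoded mRNAs were more enriched in KO cells, also adjusted over the list alone, with a median of -1.50. MT-ND2 (-2.25 ± 0.33) and MT-ND3 (-1.66 ± 0.22) were examples, the adjusted p was 5.17e-10, or adjusted p = 0.337 with an estimated correlation, and the mitochondrial share of reads was highest in the KO IPs and lowest in the KO inputs. Both sides enter this difference, with a median input change of -0.79 and a median IP change of 0.76 (KO minus control).

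Nuclear genes for mitochondrial proteins went the other way. Mitochondrial ribosomal protein mRNAs had 30 members more enriched in control and 4 in KO cells of 75 (31 and 5 adjusted over the list alone), such as MRPL32 (1.78 ± 0.16) and MRPL9 (1.26 ± 0.14). The adjusted p was 0.000168, or adjusted p = 0.337 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had 31 and 8 of 73 (33 and 9 adjusted over the list alone), with UQCR11 at 1.46 ± 0.13 and UQCRB, another complex III gene, at -2.01 ± 0.13. The adjusted p was 0.000197, or adjusted p = 0.478 with an estimated correlation. Spliceosome genes had 18 and 4 of 42, the same adjusted over the list alone, with LSM4 (1.40 ± 0.16) and the U1 protein gene SNRNP70 (1.29 ± 0.12) as examples. The adjusted p was 0.00367, or adjusted p = 0.337 with an estimated correlation. Glycolysis and hypoxia-response genes had 11 and 3 of 24 (12 and 3 adjusted over the list alone), with the mitophagy gene BNIP3 at 1.34 ± 0.15, the phosphofructokinase gene PFKP at 1.30 ± 0.14 and GAPDH at -1.11 ± 0.16. The adjusted p was 0.00468, or adjusted p = 0.337 with an estimated correlation. Proteasome genes had 13 and 7 of 30 (14 and 7 adjusted over the list alone), PSMA5 (1.38 ± 0.16) among them, with adjusted p = 0.0442, or adjusted p = 0.478 with an estimated correlation. The set test compares a list with all other genes, coding or not. Protein-coding genes as a whole had a median of 0.18, against -0.69 for the other genes. The medians of these lists lay between 0.29 (spliceosome) and 0.48 (glycolysis). Whether the lists stand apart from other coding genes was not tested.

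**Figure D2:**
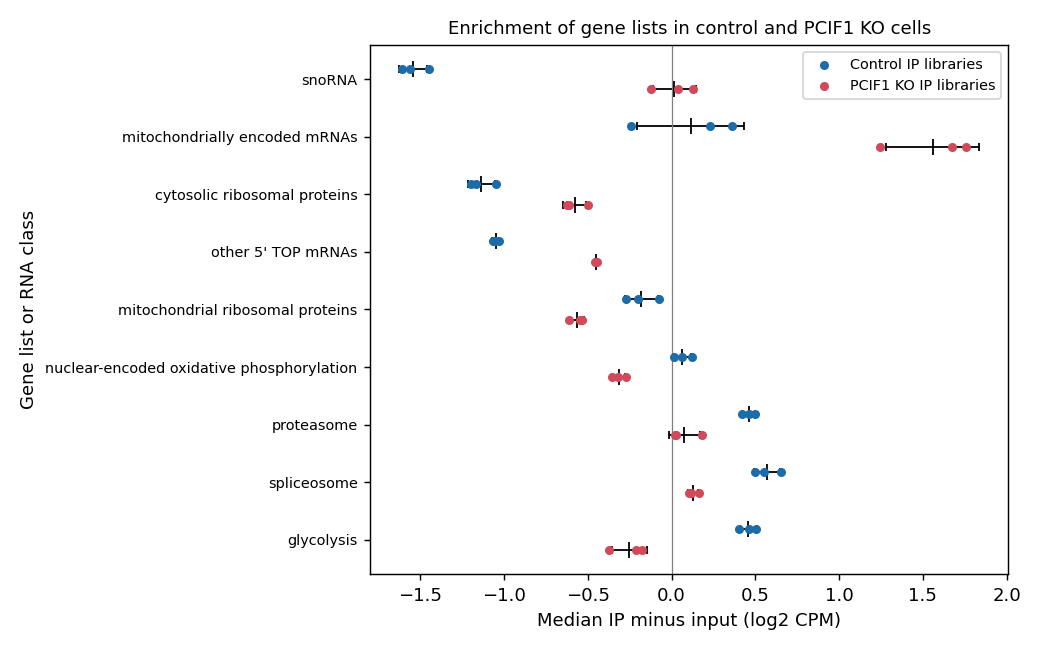
Median log2 enrichment over snoRNAs and 8 fixed gene lists, with each point 1 IP library against the mean input of its genotype, in control and KO cells, and black bars the mean and SD of 3 libraries. The 13 mitochondrially encoded mRNAs lie higher in KO than in control cells, with a median difference of -1.50 (control minus KO).

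The set test called none of the other 11 lists for this difference. Adenosine methylation writers, erasers and readers had 8 members more enriched in control and 6 in KO cells of 26 (9 and 7 adjusted over the list alone), with the reader gene HNRNPA2B1 at 1.65 ± 0.12 and the demethylase gene ALKBH5 at -1.43 ± 0.15. Cap synthesis, binding and removal genes had 6 and 4 of 27 (6 and 6 adjusted over the list alone), with the cap guanine methyltransferase gene RNMT at -0.85 ± 0.14. The value for RNMT came from a lower KO input (-0.92, KO minus control) and not from the IPs (-0.06). RNMT lies in a lowered chromosome block described below. Proliferation genes had 11 and 3 of 31, the same adjusted over the list alone (adjusted p = 0.0552, 0.0498 with each library centred on its median, and adjusted p = 0.337 with an estimated correlation), PCNA (1.12 ± 0.13) among them. Interferon-stimulated genes had 9 and 0 of 27, also adjusted over the list alone, and integrated stress response genes 10 and 5 of 25 (10 and 6), with the transcription factor gene ATF4 at 1.20 ± 0.14. Melanocyte lineage genes had 4 and 0 of 10 (4 and 1 adjusted over the list alone), including the lineage transcription factor gene MITF at 1.55 ± 0.39. Dedifferentiated melanoma genes had 5 and 2 of 23, with THBS1 at 1.39 ± 0.20, p53 targets 4 and 1 of 22, and cholesterol synthesis genes 2 and 0 of 20, each the same adjusted over the list alone. Replication-dependent histone genes had 5 and 6 of 20, also adjusted over the list alone, with a median of 0.14 against a mean of -0.18. HeLa and HEK293 lineage markers had 2 and 1 of 7, also adjusted over the list alone, with a median of 0.19 against a mean of -0.50. Keratinocyte markers (4 measured), fibroblast markers (4), leukocyte markers (3) and endothelial markers (4) were too few to test. Among them ITGA6 (0.60 ± 0.14), TWIST2 (0.67 ± 0.22), CD68 (0.67 ± 0.18) and TIE1 (1.18 ± 0.18) were more enriched in control and COL6A3 (-1.59 ± 0.47) in KO cells.

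The IP libraries were also compared directly, KO minus control, which leaves the input libraries out of the difference. Mitochondrially encoded mRNAs rose in 10 of 13 cases and fell in 0, ribosomal protein mRNAs rose in 51 and fell in 11 of 79, and the other TOP mRNAs rose in 14 and fell in 2 of 20. Adjusted over the list alone the counts were 10 and 0, 51 and 12, and 14 and 2. Their set tests gave adjusted p = 0.000901, 2.54e-09 and 5.15e-05, and adjusted p = 0.404, 0.282 and 0.244 with an estimated correlation. Mitochondrial ribosomal protein mRNAs fell in 39 and rose in 7 of 75, nuclear-encoded oxidative phosphorylation genes fell in 42 and rose in 10 of 73, and interferon-stimulated genes fell in 13 and rose in 1 of 27. Adjusted over the list alone the counts were 39 and 7, 43 and 10, and 13 and 1. Their adjusted p-values were 5.15e-05, 3.44e-05 and 0.0181, with adjusted p = 0.282, 0.331 and 0.244 with an estimated correlation. The fall of interferon-stimulated genes in the IPs (median -0.62) joins a lower median in the KO inputs (-0.32), which the set test did not call. It therefore cannot be read as lost enrichment alone. Spliceosome genes fell in 23 and rose in 6 of 42 and glycolysis genes fell in 16 and rose in 4 of 24, the same adjusted over the list alone. Their adjusted p-values were 0.00037 and 0.0007, with adjusted p = 0.282 for both with an estimated correlation. In all, 7843 genes differed, 3675 higher and 4168 lower in KO IPs, and 1603 and 7482 when centred on ribosomal protein mRNAs, which put the median at -0.56 and that of the other TOP mRNAs at -0.000416. The set test called none of the other 11 tested lists. Groups did not overlap for 8744 genes (54.6%), against 10% by chance.

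Since m6Am needs an adenosine at the first transcribed position, enrichment was compared by the first base of the gene record. Genes starting with A exceeded the others by 0.29 ± 0.0114 in control cells and by 0.16 ± 0.0165 in KO cells (mean difference in log2 enrichment, SD across 3 IP libraries against the shared mean input). The difference of 0.12 was larger than the spread between libraries, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 can give. Of 6216 genes starting with A, 1179 (19.0%) were called less enriched in the KO than in control cells, against 1338 of 9687 others (13.8%), an odds ratio of 1.46 (95% interval 1.34 to 1.59, two-sided Fisher's exact test p = 7.36e-18, across genes, which are not independent replicates). With the start of the canonical transcript of protein-coding genes, a choice made after the data were seen, the difference was 0.30 (0.56 in control and 0.25 in KO cells). There, 27.6% of A-start genes and 13.4% of the others were called so (odds ratio 2.46, Fisher's exact test p = 4.80e-84). Median enrichment of these coding genes in control and KO cells was 0.33 and 0.00 for 5549 A starts, -0.50 and -0.37 for 1366 C starts, -0.16 and -0.21 for 5061 G starts and -0.30 and -0.01 for 71 T starts. Counting an A within 2 bases on either side as a start brought the difference to 0.02, with 10944 of 15903 genes then in the A class.

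**Figure D3:**
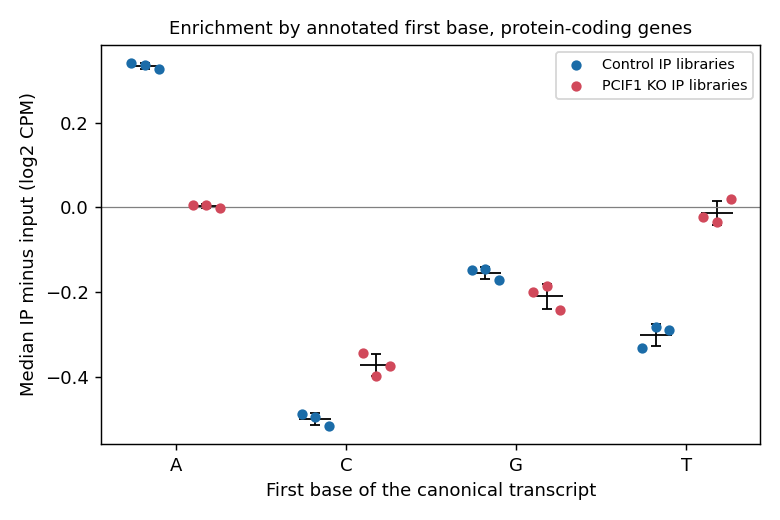
Median log2 enrichment (IP minus mean input) of protein-coding genes by the first base of the canonical transcript, with each point 1 of 3 IP libraries per genotype, and black bars their mean and SD. Genes starting with A lie at 0.33 in control cells and at 0.00 in KO cells, and genes starting with C lie below 0 in both.

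Input libraries were compared to see which 5' ends changed in abundance in the KO before any pull-down. The non-coding RNA MIR4527HG rose from 1.24 ± 0.416 CPM to 99 ± 14.6 CPM, a log2 change of 6.37 ± 0.25 (adjusted p = 5.04e-12), and LINC00665 rose from 2.52 ± 0.881 CPM to 107 ± 2.36 CPM (5.46 ± 0.28). The small GTPase gene RAB17 (3.53 ± 0.25), the matrix proteoglycan gene BGN (2.53 ± 0.20), the melanoma-secreted protein gene MIA (2.02 ± 0.23), the Wnt antagonist gene DKK3 (from 8.31 ± 2.08 to 32.6 ± 2.45 CPM) and the carnitine acetyltransferase gene CRAT (1.99 ± 0.19) also rose. HBG2 (3.16 ± 0.17), HBE1 (2.88 ± 0.12) and OR51B4 (2.14 ± 0.31), in the beta-globin region of chromosome 11, have overlapping records, and reads cannot be assigned among them. The hypoxia-induced carbonic anhydrase gene CA9 fell from 35.2 ± 3.118 CPM to 6.67 ± 2.11 CPM (-2.45 ± 0.24, adjusted p = 8.02e-07). The matrix gene TGFBI (-2.24 ± 0.14), the sphingosine kinase gene SPHK1 (-2.16 ± 0.22), the calcium-binding protein gene S100A4 (-2.13 ± 0.20), ADAMTSL4 (-2.04 ± 0.24) and the 14-3-3 sigma gene SFN (-2.03 ± 0.16) fell as well. COSMOC (-2.43 ± 0.31), MIR6843, which lies in CLU (-2.28 ± 0.18), FAM78A (-2.07 ± 0.21) and LANCL1 (-1.95 ± 0.21) completed the 10 largest decreases.

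In all, 1798 of 16009 genes differed between the inputs, 890 higher and 908 lower in the KO, and 1177 without control input replicate 3. Groups did not overlap for 5080 genes (31.7%), against 10% by chance. Of the fixed lists the set test called 1. Mitochondrially encoded mRNAs fell in 9 of 13 cases and rose in 0 (12 fell adjusted over the list alone), with a median of -0.79, adjusted p = 5.11e-10, and adjusted p = 0.458 with an estimated correlation. MT-ND2 (-1.43 ± 0.23) and MT-CO3 (-1.41 ± 0.16) were examples. Among the lists with no call, dedifferentiated melanoma genes fell in 5 and rose in 2 of 23 (6 and 2 adjusted over the list alone), with the matrix gene TNC at -0.70 ± 0.12. Melanocyte lineage genes fell in 3 and rose in 1 of 10 (4 and 1 adjusted over the list alone), with PAX3 at 0.96 ± 0.16 and ERBB3 at -1.82 ± 0.44. Replication-dependent histone genes rose in 4 and fell in 1 of 20, the same adjusted over the list alone, with H1-2 at 1.33 ± 0.12 and H1-5 at -5.98 ± 0.71. H1-5 is not among the 10 largest decreases above, since it missed the rule's mean log2 CPM of at least 3 or its no-overlap condition. The size of its change is therefore uncertain. The p53 targets rose in 2 and fell in 3 of 22, the same adjusted over the list alone, with the cell cycle inhibitor gene CDKN1A down by 1.30 on the log2 scale. Proliferation genes rose in 2 and fell in 2 of 31, the same adjusted over the list alone. Interferon-stimulated genes rose in 0 and fell in 3 of 27 (1 and 5 adjusted over the list alone), with a median of -0.32. Their set test gave adjusted p = 0.158, and adjusted p = 0.458 with an estimated correlation.

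Input changes were grouped along chromosomes. In runs of neighbouring protein-coding genes, a rule chosen after the data were seen found 7 blocks that hold 263 of 8626 genes, where the highest of 200 shuffled orders held 49. On chromosome 18 the 39 genes from USP14 to ROCK1 (158383 to 21111813) had a median change of -0.63, and the 53 genes from CTIF to PARD6G (48539031 to 80247514) one of 0.53. The 50 genes from SOX12 to RRBP1 on chromosome 20 (325552 to 17682295) had a median of -0.43. The 2 proliferation genes that fell, TYMS (-0.85) on chromosome 18 and PCNA (-0.89) on chromosome 20, lie in these lowered blocks. Of all 16009 genes, 478 lie within the blocks, and 197 of these are among the 1798 that differed between the inputs.

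**Figure D4:**
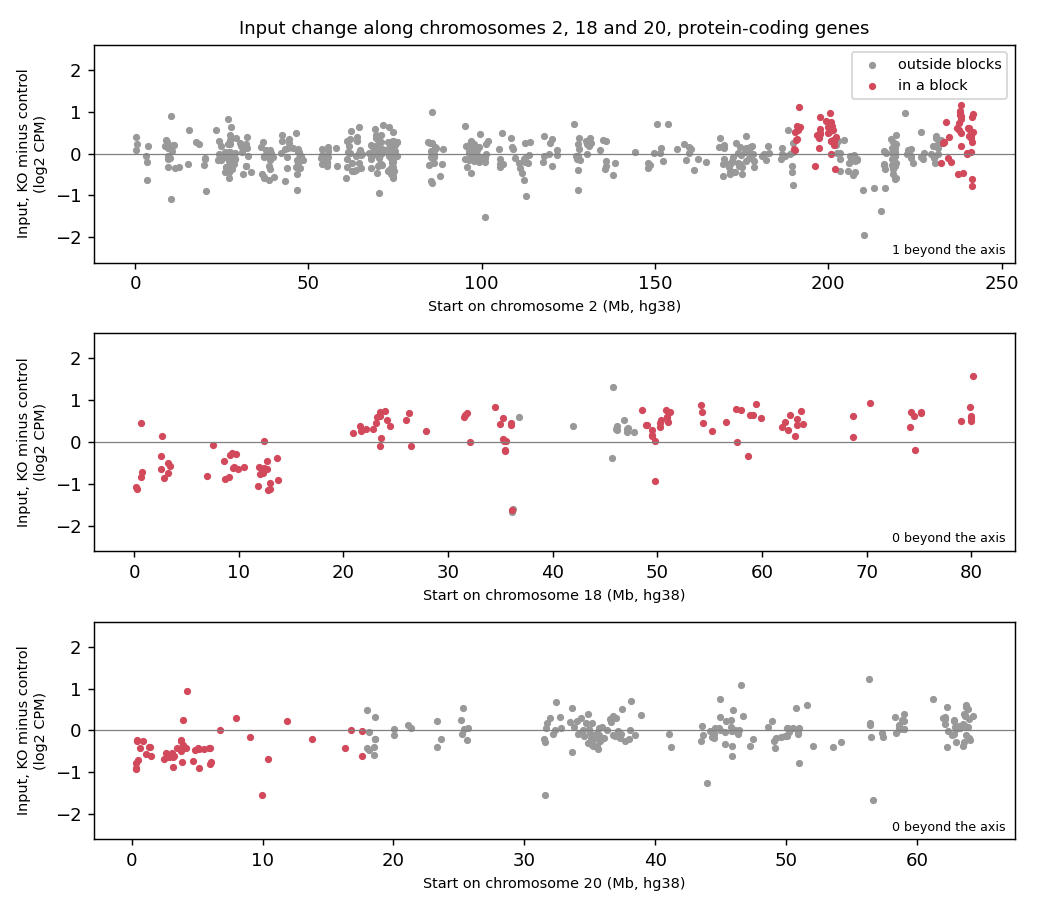
Log2 input change (KO minus control) by position (hg38) on chromosomes 2, 18 and 20, with each point 1 protein-coding gene, red in a block and grey outside. Chromosome 18 has its first part below 0 (median -0.63 from USP14 to ROCK1) and its last part above 0 (0.53 from CTIF to PARD6G).

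Whether 5' ends that were less enriched in the KO also changed in abundance was asked last. The 2522 genes more enriched in control cells had a median input change of 0.0489, against -0.0315 for all other genes, a difference of 0.0805. The same input libraries enter both quantities, and 50 simulations with no input change gave 0.0614 ± 0.00490 (SD). The simulations drew each gene independently and held the IPs fixed, so that this SD leaves out spread shared by the genes of a library. Across the input libraries the difference had an SD of 0.0530, more than the distance between 0.0805 and 0.0614. The simulations therefore do not show an input change beyond the shared inputs. With the class taken from the IP libraries alone, the difference was -0.157. A lower input in the KO also lowers the KO IP, so that this class favours genes whose input fell. Of the 2522 genes, 427 (16.9%) changed in the inputs, against 1371 of the others (10.2%) and 14.4% of others matched on mean expression. In 251 of them the input rose in the KO, where independent lists would share 140.2, and in 176 it fell, where they would share 143. A raised KO input itself moves a gene towards this class. The lists are therefore not independent, and these counts decide nothing. Of the 4168 genes in the class from the IP libraries alone, 655 (15.7%) changed in the inputs, against 9.65% of the others, and the input rose in 106 and fell in 549 of them. The choice of that class favours such a fall, so that these counts do not tell whether lost enrichment goes with abundance. A class from 1 column number (a difference of at least 1), with the input change tested in the other numbers, was chosen after the data were seen and covers only genes with a mean log2 CPM of at least 3 (1065, 916 and 1093 in the class and 8581, 8730 and 8553 others). For numbers 1, 2 and 3, the input changed in 7.23%, 4.15% and 9.88% of the class and in 6.20%, 4.31% and 8.40% of the others. It rose in 37, 15 and 58 genes of the class and fell in 40, 23 and 50.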

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

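In this part, the tests of rescaling and of input-like background were chosen only after the result was seen. The difference in enrichment between control and KO cells was flagged by the test of the difference itself. It passed for 4605 of 16009 genes and, with the preset correlation, for 8 of the fixed gene lists (0 with an estimated correlation). In 457 genes the enrichment was called in opposite directions in control and KO cells and the difference was called too.

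Of the 10 splits of the 6 pairs of input and IP columns into 3 and 3, only the real one, 1 of 10, gave as many as 4605 genes, and the highest other gave 0. For control enrichment it was also 1 of 10 splits, with 8944 genes against 0 in the highest other, and for KO enrichment 1 of 10, with 9512 against 1. The input change gave 1798 against 0 and the IP change 7843 against 0, again in 1 of 10 splits each. With 10 splits, no share under 0.05 can be reached.

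The pattern a reader may want to follow first is the higher enrichment of mitochondrially encoded mRNAs and snoRNAs in KO than in control cells. Mitochondrial mRNAs lay above the KO input, and their difference joins a fall in the inputs (median -0.79, KO minus control) to a rise in the IPs (0.76), while snoRNAs went from -1.54 (SD 0.0834) in control cells to 0.0164 (SD 0.127) in KO cells, within 1 SD of the input level. Lower depth of the KO IPs is argued against, since after thinning every library to 1753164 reads the mitochondrial median was still -1.42 (SD 0.429, control minus KO) and that of snoRNAs -1.57 (SD 0.118). A larger input-like background in the KO IPs would bring enrichment towards 0, but the mitochondrial mRNAs stood at 1.56 (SD 0.277) in KO cells, which argues against it for them. The snoRNA values go with such a move, but as the whole cause it is argued against, since ribosomal protein mRNAs, at -1.14 in control cells, stayed at -0.58 (SD 0.0696) in KO cells. A plain rescaling of the KO IPs would move all genes alike, and is argued against as the whole cause by coding genes with starts other than A. The 6498 protein-coding genes starting with C, G or T differed by 0.0271 (SD 0.0286, control minus KO), and mitochondrial mRNAs lay -1.47 (SD 0.443) and snoRNAs -1.59 (SD 0.177) from them. From ribosomal protein mRNAs, which were less depleted in KO than in control cells, the distances were -0.887 (SD 0.450) and -1.001 (SD 0.228). The distance of the mitochondrial mRNAs is not clearly beyond its spread there, so that this reference alone cannot tell for them. All SDs in this paragraph cover the IP libraries only, with the mean input of each genotype held fixed. Whether loss of PCIF1 itself, a different yield of the exonuclease step, or another difference between the cell lines lies behind the difference was not tested.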

How the results depend on the processing

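Settings chosen after the data were seen are voom, thinning, GC correction, coding genes only, genes outside blocks, column-number blocks and classes, and the canonical start. The reported filter removed no gene, so that a fit without it is the same, and blocks or classes by replicate letter were not run because columns are not tied to letters. Except as listed here, counts of called genes stayed within 1.5 times the reported ones. Thinning to 1753164 reads gave 7995, 8348, 3589, 1324 and 6593 genes (enrichment in control cells, enrichment in PCIF1 KO cells, PCIF1-dependent enrichment, input change in PCIF1 KO, IP change in PCIF1 KO) and voom on the reads gave 9918, 9351, 4927, 2481 and 7821. A log2 difference of at least 1 left 5154, 5757, 2180, 630 and 3646, by construction. Leaving out each library gave 8041 to 9338, 8745 to 9423, 3815 to 4764, 1177 to 2201 and 6732 to 7964; the input count of 1177 came without control input replicate 3, and the cause was not tested. Over the 5 contrasts, 23 list calls became 0 with an estimated correlation and 60 with fry, which does not compare a list with other genes. Centring each library on its median gave 24, with proliferation genes added in PCIF1-dependent enrichment (adjusted p = 0.0498, and adjusted p = 0.337 with an estimated correlation).

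Same-numbered columns were not treated as pairs. The labels pair input and IP by letter, nothing ties numbers to letters, and 8 of 12 pairs, not all, correlated above 0.1 (-0.0753 to 0.244). In 10 of 12 pairs the best correlation was with the same number, a hint of a shared number from the data, not the design. Every pair of input and IP within a genotype was among these (0.0697 to 0.244), and the misses were between genotypes for number 2. A replicate block by column number gave 9154 and 9750 genes for enrichment in control cells and enrichment in PCIF1 KO cells, 5088 for PCIF1-dependent enrichment, 2216 for input change in PCIF1 KO and 8173 for IP change in PCIF1 KO, and a block within genotype 9215, 9800 and 5176 for the first 3. With the column block the input change also called the replication-dependent histone list (adjusted p = 0.0430, and adjusted p = 0.682 with an estimated correlation and no block; median 0.18, mean -0.0460); no other list call changed.

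The first-base difference of 0.12 was 0.0242 with an A within 2 bases, 0.16 with the stricter filter, 0.24 with C before the A, 0.29 with the canonical start and 0.30 for its coding genes. The input difference of dependent genes (0.0805) was -0.157 with the class from the IP change alone, and 0.0212, -0.0279 and 0.0404 with classes from column numbers 1, 2 and 3. The class from the IP change favours a lower KO input by its definition, while the reported class favours a higher one. Other causes were not tested. Reversed under centring on ribosomal protein mRNAs were SQLE (0.36) and PCIF1 (0.15) in control enrichment, KRT8 in KO enrichment (0.45) and PCIF1 in the IP change (-0.12), by the shift of all genes. The value for PCIF1: PCIF1-dependent enrichment ranged from -0.0272 (without KO IP replicate 3) to 0.23, was -0.0685 thinned and -0.0060 after GC correction, and NEFL in control enrichment was -0.34 thinned, and neither reported value passed the test. On reads simulated at 1 setting, 42% of 1.5-fold changes in PCIF1-dependent enrichment, planted in better-covered genes, were recovered, and depth was not varied there.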

Other observations

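In this part, the RNA classes, the chromosome blocks, and the tests of regional differences, of raised-block genes that lost no enrichment and of gene order were chosen only after the results were seen. Beyond snoRNAs, other short and non-coding RNA classes were more enriched, or less depleted, in KO than in control cells. Against input, the median of microRNA genes was -1.52 in control and -0.38 in KO cells, so that it stayed below input. The medians of mitochondrial tRNAs (1.05), small nuclear RNAs (1.18), processed pseudogenes (0.91) and long non-coding RNAs (0.39) lay above input in KO cells. Of 22 mitochondrial tRNAs, 18 were more enriched in KO and 0 in control cells, with a median difference of -1.74 (camera adjusted p = 1.47e-13). Small nuclear RNAs had 13 and 0 of 51 (adjusted p = 5.33e-06), microRNA genes 204 and 15 of 459 (adjusted p = 2.46e-18), processed pseudogenes 102 and 4 of 474 (adjusted p = 1.13e-08) and long non-coding RNAs 244 and 71 of 1987 (adjusted p = 0.00179). Protein-coding genes went the other way, with 2403 more enriched in control and 1225 in KO cells of 12047 (adjusted p = 7.01e-12). All of these calls hold with an estimated correlation. Reads at starts that lie in or near another gene on the same strand are uncertain here too, as for the snoRNAs. How many members of each class this concerns was not counted, so that the class values may partly be those of overlapping genes. Lower depth of the KO IPs was not tested for these classes. The median of long non-coding RNAs, -0.33, turns to 0.23 when libraries are centred on ribosomal protein mRNAs. Coding genes held 92.8% of the reads in control IPs and 85.03% in KO IPs, against 87.0% and 87.4% in the inputs.

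Enrichment was largely shared by control and KO cells. GC content of the transcript start as the whole cause is argued against, since the correlation across genes was 0.665 after a correction for GC in each library and 0.667 before. Internal m6A is a candidate explanation for part of it, since the 10225 genes with a DRACH motif, the sequence context of m6A, in their first 100 bases lay above the 5096 genes without one in all 3 KO IPs, by 0.36 to 0.39 on the log2 scale, and by 0.24 on average in the control IPs. After the GC correction the difference was 0.17 to 0.18 in KO and 0.10 in control IPs, so that part of it goes with base composition. What enriches genes without a motif stays open.

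The chromosome blocks in the input change had the same direction in the IP libraries in the 7 blocks, and in 4 of them the median IP change was at least 0.5 times the input change. In the others it was smaller, at 0.04 against 0.31 on chromosome 16, and 0.21 against 0.48 and 0.09 against 0.43 on chromosome 2. A copy-number or other regional difference between the control and KO lines is a candidate explanation. An input change of any cause would carry into IPs of the same cells, so that this agreement cannot tell such a difference from other causes. The regional difference as a hypothesis was found and tested on the same data, and DNA was not analysed here. Loss of the methylation is argued against for those genes of the 5 raised blocks that lost no enrichment in the KO, since in 5 of 5 they kept at least 0.5 times the block's change (0.49 on chromosome 18 from CTIF to PARD6G). The inputs enter the choice of these genes too, which favours a lower KO input and so works against a rise. For the other block genes, those of the lowered blocks included, it cannot be told apart, because the odds ratio of PCIF1-dependent calls in blocks against elsewhere, 1.24, has a wide interval (0.941 to 1.63, Fisher's exact test p = 0.118). Chance order is argued against, since 0% of 200 shuffled orders held as many genes in blocks.

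In a refit without the 478 genes within the blocks, 1531 genes differed between the inputs and 7561 between the IPs.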
